A study of Homo sapiens with 9 samples.

How the data were processed

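Total RNA from BT-549 cells was measured on Affymetrix Human Gene 2.0 ST arrays in 9 samples, 3 each of mock (lipid reagent without RNA), negative control small RNA and miR-150-5p mimic. The medium was replaced at 24 h and RNA, extracted with Trizol, was collected at 72 h, with 50 nM of either small RNA. Per the labels, 1 ug of RNA per sample was labelled with the FlashTag biotin kit. That kit is usually used for small RNA, and how it was applied to whole transcripts is not given in the sources used here. The values are log2 signals made by the authors with RMA, which corrects the background, brings the arrays to near-identical distributions and sums each feature's probes; the RMA version, software and array definition file are not given in the sources used here. The deposited table held 9 arrays with 0 missing values and no filter on features was seen. Samples were grouped by the labels' treatment.

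Features were given gene symbols with the platform's annotation table, in which 16098 features of the array had exactly 1 symbol. The other 37519 had no single symbol here, and any with several symbols were not counted apart from those with none. All 16098 gene IDs matched a RefSeq gene table of the GRCh38.p14 assembly, used for names only. For the 779 genes with more than 1 feature, the feature with the highest mean over all 9 arrays stood for the gene, which left 14884 genes, with no filter on signal. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 9 arrays with 1 mean per group, so that all groups share 1 estimate of the spread, with 6 residual and 9.60 total degrees of freedom. The p-values are two-sided and were adjusted by Benjamini and Hochberg over the genes of each comparison, and a gene counted as changed at an adjusted p under 0.05. The comparisons were mimic against negative control, mimic against mock, negative control against mock, mimic against the mean of both control groups, and the genes changed the same way against each control. The number of arrays limits the precision.

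Of 36 gene lists written from general knowledge, with 933 symbols of which 507 were measured, 34 had at least 5 measured members and were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 34 lists. Of the others, the replication histone list had 0 measured members and the antigen presentation list 4. The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took, for each comparison against the negative control or mock, the 10 largest rises and 10 largest falls (5 and 5 for negative control against mock) among changed genes whose arrays did not overlap between the groups. It left out microRNA, small nucleolar and uncharacterised loci, which are given as counts. It added MYB, NOTCH3, EGR2, ZEB1 and CXCR4 and up to 4 members with the largest change from each list described. A list of aminoacyl-tRNA synthetase genes and one of amino acid response genes were added after seeing the data.

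The replicate numbers were checked for pairing by the correlation across genes of the arrays' deviations from their group means. Negative control and mock arrays of the same number had r = 0.15, 0.23 and 0.15. Each negative control array had its best match in the mock array of its number. These numbers may thus pair the samples, on evidence from the values and not from the labels. Mock 2 and negative control 2 also had the highest mean of small nucleolar and Cajal body RNAs in their groups (6.78 and 6.83). Whether that alone gives these r was not tested. Mimic arrays had r from -0.29 to -0.054 with arrays of their number. How far comparisons share chance values through the arrays they have in common was set against 100 simulations with unchanged, independent groups. Added after seeing the data were 100 in which same-numbered negative control and mock arrays were correlated as observed.

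The alternatives were a second quantile normalization, centring on array medians, filters at the 25th percentile and at the median of signal, the mean of a gene's features, all features with or without a symbol, array weights, a mean-variance trend with robust variance, a fit on the 6 arrays compared, the replicate block, an adjusted p under 0.01, a minimum of 1.5-fold, leaving out each array, and for lists an estimated correlation and fry. A covariate from the mean of the small nucleolar and Cajal body RNAs, leaving out mock 2 and negative control 2 together, an exact permutation of list means, and the replicate block for genes changed in opposite ways were added after seeing the data. The medians of 9 lists were set against those of 10000 random lists matched on mean signal. Tests of genes with seed matches to miR-150-5p in 3' UTRs were planned and not run, because no 3' UTR sequence was used here. The pipeline was tested on simulated data of 14884 genes. It recovered 45 of 100 genes planted at a log2 change of 0.5 and 97 of 100 planted at 1. There were 10 false calls among 154, and 0 calls between unchanged groups. The simulated noise was normal and independent between genes and arrays, with the spread of the fit, unlike the real arrays. These rates may therefore not hold for the real arrays.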

Results

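BT-549 is a human triple-negative breast cancer cell line, so called because such tumours lack the estrogen and progesterone receptors and extra copies of HER2. The cells were transfected with a synthetic mimic of miR-150-5p, with an unrelated negative control small RNA, or with the lipid reagent without RNA (mock), each in triplicate. The small RNAs were used at 50 nM, and RNA was collected at 72 h. Each of the 9 RNA samples was read on a whole-transcript array, giving a log2 signal per feature, and 14884 genes with a symbol were tested. Array medians lay between 2.43 and 2.48. Pearson's r across features, which are not independent replicates, was 0.981 to 0.989 for pairs of arrays within a group and 0.977 to 0.986 for pairs between groups. The labels do not say that the 3 samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. Changes are given as log2 ± SE from limma with n = 3 arrays per group. Where a call was lost when arrays were left out 1 at a time, those arrays are named with the highest adjusted p. This was not done for values quoted beside another comparison, or for genes listed as changed the same or opposite ways.

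The feature of MIR150, the gene of the microRNA itself, averaged 2.71 ± 0.12 (SD) in mock, 2.80 ± 0.22 in the negative control and 2.62 ± 0.44 in the mimic arrays, n = 3 each. It changed in no comparison, and since the mimic is a mature microRNA added to the cells, it checks nothing about the labels.

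The comparison of the mimic with the negative control asks what miR-150-5p does beyond the entry of any small RNA. CFAP47, named for cilia and flagella, rose most, by 1.75 ± 0.088 (3.36-fold, n = 3 per group, adjusted p = 5.9e-05). The secreted matrix protein gene ADAMTSL1 (1.54 ± 0.13, adjusted p = 0.00091), CRIM1 (1.53 ± 0.14, adjusted p = 0.0011), a membrane protein that binds bone morphogenetic proteins, and MET, the receptor of hepatocyte growth factor, at 1.22 ± 0.094, also rose. CFAP47, CRIM1 and MET are among 41 genes that the negative control changed the opposite way against mock, of which CFAP47 also rose in the mimic against mock. MET was at -1.57 in the negative control against mock and at -0.35 in the mimic against mock (adjusted p = 0.075). CD109, a membrane glycoprotein that binds TGF-beta, fell by 1.63 on the log2 scale (3.1-fold lower, SE 0.11, adjusted p = 0.00026), and its other feature gave -0.23. Among the largest falls were also SLFN5 (-1.64 ± 0.18), of the Schlafen family, HEG1 (-1.58 ± 0.23), a membrane protein of endothelial junctions, and IGFBP5 (-1.39 ± 0.14), a binding protein of insulin-like growth factors.

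The other genes with the largest rises were SESN2 (1.36 ± 0.23, adjusted p = 0.060 without mimic 1), a stress-induced sestrin, PAPPA2 (1.34 ± 0.17), a protease that cleaves IGF-binding proteins, and THOC5 (1.14 ± 0.13), of the mRNA export complex THO. With them rose RRS1 (1.12 ± 0.16), of ribosome assembly, VLDLR (1.11 ± 0.11), a lipoprotein receptor, and MSANTD3-TMEFF1 (1.18 ± 0.10), a readthrough transcript of a pair of neighbouring genes. The other largest falls were SLC49A4 (-1.66 ± 0.17), SMIM3 (-1.50 ± 0.20), OSTF1 (-1.50 ± 0.18) and GXYLT2 (-1.47 ± 0.20). PNMA1 (-1.44 ± 0.13) and GSR (-1.41 ± 0.11), glutathione reductase, fell next. THOC5, VLDLR, MSANTD3-TMEFF1 and PNMA1 are also among the genes that the negative control changed the opposite way against mock.

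Of the 14884 genes, 473 changed, with 262 rising and 211 falling, and 2378 had an unadjusted p under 0.05. Of the 473, 322 changed at least 1.5-fold and 69 at least 2-fold, and 23 were microRNA, small nucleolar or uncharacterised loci (12 rose and 11 fell). In all 473 the 3 arrays of one group lay above the 3 of the other, as in 18.6% of all genes tested and in 10% by chance. The balance of rises and falls depended on the scaling, since 176 rose and 289 fell when the arrays were quantile-normalized once more (37.8% rising, against 55.4%). The count was 206, 234 and 199 without mimic 1, 2 and 3, 263 and 221 without negative control 1 and 3, and 314 without mock 1.

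Of 5 genes fixed beforehand as known or proposed targets of miR-150, ZEB1, a transcription factor that represses epithelial genes, fell by 0.36 on the log2 scale against the negative control (SE 0.076, adjusted p = 0.036), with adjusted p up to 0.11 without each array except negative control 2. MYB (-0.06 ± 0.10, adjusted p = 0.84), a transcription factor of blood cell progenitors, the receptor gene NOTCH3 (0.10 ± 0.21, adjusted p = 0.88) and the chemokine receptor gene CXCR4 (-0.22 ± 0.11, adjusted p = 0.36) did not pass. EGR2 was not analysed here. MYB and CXCR4 read near the array median, at 2.44 and 2.61 in the negative control. In the list of 19 measured reported targets, 1 rose, 2 fell and 16 did not pass (1 rose and 2 fell adjusted over the list alone). The members that passed were HMGA2 (1.01 ± 0.15), a chromatin protein of embryonic tissue, which rose, and MMP14 (-0.69 ± 0.11, adjusted p = 0.054 without mimic 1), a membrane-bound matrix metalloproteinase, and ZEB1, which fell. The list had 9 members above 0 and 9 below, with a median of 0. For reported targets adjusted p = 0.62, against adjusted p = 0.76 with an estimated correlation. The mean, -0.0066, and the test pointed down while the median was at 0.

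**Figure D1:**
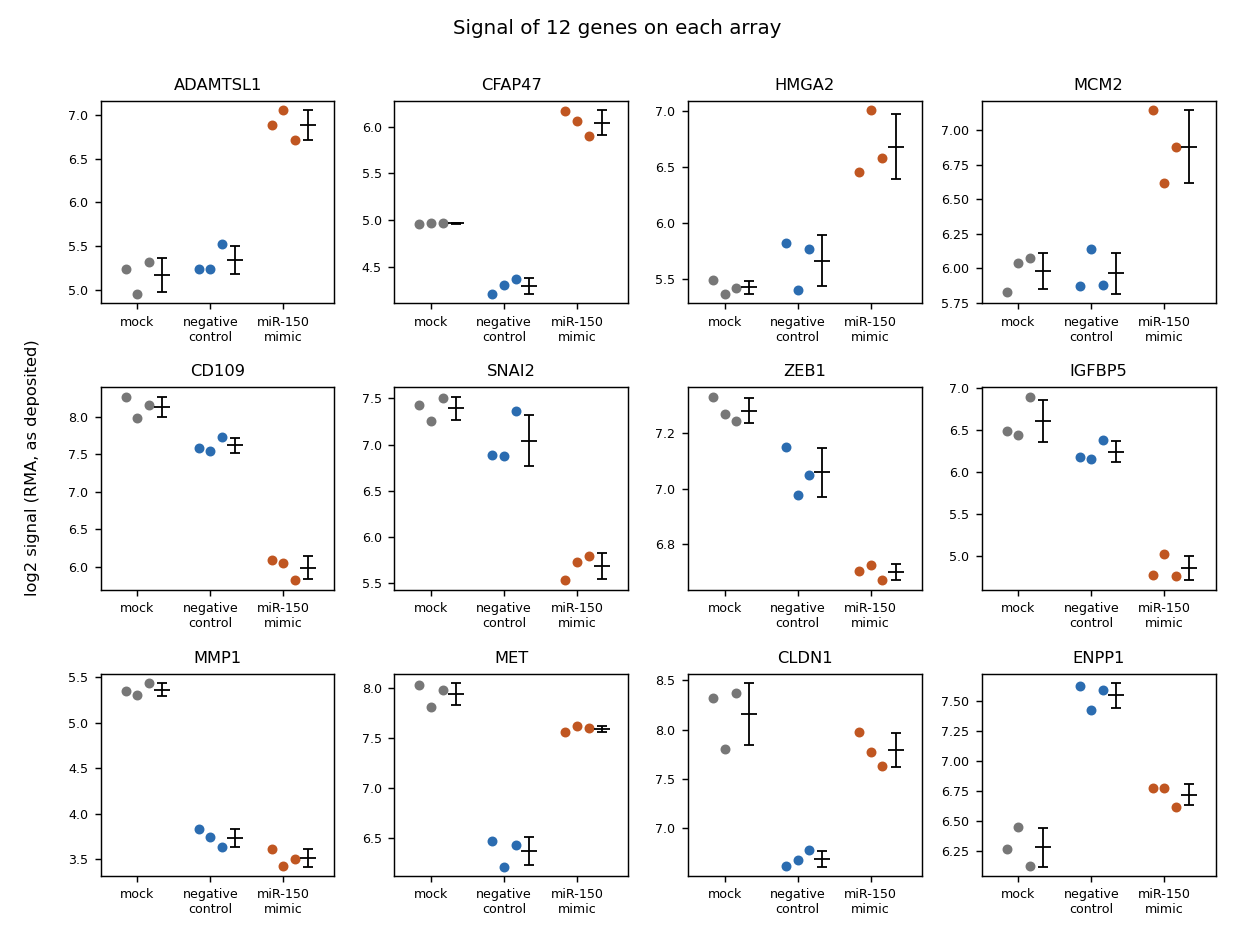
Signal of 12 genes on each array (y axis, log2 RMA signal as deposited; each point is 1 array, bars are mean ± SD, n = 3 per group, and each panel has its own scale). The 3 mimic arrays lie above all control arrays for ADAMTSL1, CFAP47, HMGA2 and MCM2 and below them for CD109, SNAI2, ZEB1 and IGFBP5, whereas for MET and CLDN1 the 3 negative control arrays lie below the rest.

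Genes of DNA replication and the G1/S transition were called upward by camera, as were the lists of G2/M and DNA repair genes. Of 29 measured, 8 rose, 1 fell and 20 did not pass (14 rose and 1 fell adjusted over the list alone). The largest were CCNE2 (1.10 ± 0.19, adjusted p up to 0.070 without negative control 1 or 3, or mimic 1 or 3), a cyclin of S phase entry, MCM2 (0.92 ± 0.14) and MCM4 (0.67 ± 0.082), of the replicative helicase, and CDC6 (0.84 ± 0.14, adjusted p up to 0.059 without negative control 1, or any mimic array), which loads it. The member that fell was RRM2 (-0.63 ± 0.10, adjusted p up to 0.057 without mimic 2 or 3), a subunit of ribonucleotide reductase, named after its value was seen. The list had 26 members above 0 and 3 below, with a median of 0.34. For G1/S genes adjusted p = 1.2e-09, against adjusted p = 0.36 with an estimated correlation. Of 41 measured G2/M genes, 2 rose, 0 fell and 39 did not pass (5 rose and 0 fell adjusted over the list alone). RANGAP1 (0.81 ± 0.10) and GTSE1 (0.40 ± 0.084, adjusted p up to 0.12 without each array except mock 2 and 3), the latter named after its value was seen, were the 2 that rose. This list had 32 members above 0 and 9 below, with a median of 0.17. For G2/M genes adjusted p = 0.00069, against adjusted p = 0.64 with an estimated correlation, and adjusted p = 0.060 without negative control 3. The G2/M median lay at percentile 96.57 of 10000 random lists matched on signal. Of 15 DNA repair genes, 1 rose, 0 fell and 14 did not pass (2 rose and 0 fell adjusted over the list alone). The gene that rose was XRCC2 (0.65 ± 0.14, adjusted p up to 0.14 without each array except mock 3, and negative control 2), of homologous recombination. DNA repair had 11 members above 0 and 4 below, with a median of 0.18. For repair genes adjusted p = 0.039, against adjusted p = 0.64 with an estimated correlation, and adjusted p up to 0.21 without negative control 3, or mimic 1 or 3. The DNA repair list also missed with the arrays quantile-normalized once more (adjusted p = 0.15).

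Lists of the ribosome were called upward as well. Of 43 measured ribosomal protein genes, 3 rose, 0 fell and 40 did not pass (6 rose and 0 fell adjusted over the list alone). The 3 were RPL32 (0.88 ± 0.19, adjusted p up to 0.15 without each array except negative control 1), RPL34 (0.53 ± 0.095, adjusted p up to 0.070 without negative control 1 or 3, or mimic 1 or 2) and RPL35A (0.59 ± 0.12, adjusted p up to 0.12 without each array except negative control 2), of which RPL34 and RPL35A were named after their values were seen. The list had 42 members above 0 and 1 below, with a median of 0.26. For ribosomal proteins adjusted p = 1.2e-09, against adjusted p = 0.47 with an estimated correlation. Of 16 MYC-linked ribosome biogenesis genes, 2 rose, 0 fell and 14 did not pass (11 rose and 0 fell adjusted over the list alone). The 2 were RRS1, at 1.12 ± 0.16, and RRP12 (0.84 ± 0.18, adjusted p up to 0.14 without each array except mock 2 and 3). This list had 15 members above 0 and 1 below, with a median of 0.38. For biogenesis genes adjusted p = 3.5e-08, against adjusted p = 0.36 with an estimated correlation. The small nucleolar and Cajal body RNAs averaged 5.62, 6.78 and 5.64 on mock 1 to 3, 5.91, 6.83 and 5.87 on negative control 1 to 3, and 6.43, 5.95 and 6.75 on mimic 1 to 3, with an SD of 0.67, 0.54 and 0.40 within the groups.

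Lists of mesenchymal genes, markers of stem-like tumour cells and interferon-induced genes were called downward. Of 13 measured mesenchymal genes, 0 rose, 3 fell and 10 did not pass (0 rose and 3 fell adjusted over the list alone). The 3 were SNAI2 (-1.36 ± 0.14), TWIST1 (-0.61 ± 0.098, adjusted p up to 0.054 without mimic 1 or 3) and ZEB1, transcription factors that drive loss of epithelial character. The list had 5 members above 0 and 8 below, with a median of -0.13. For mesenchymal genes adjusted p = 0.039, against adjusted p = 0.64 with an estimated correlation, and adjusted p up to 0.13 without mock 2 or 3, negative control 3, or mimic 1 or 3. Of 10 stem and cancer markers, 0 rose, 2 fell and 8 did not pass (0 rose and 3 fell adjusted over the list alone). The falls were those of SOX9 (-0.86 ± 0.17, adjusted p up to 0.098 without each array except mock 2 and 3, and negative control 2), a transcription factor of progenitor cells, and CD24 (-0.79 ± 0.14, adjusted p = 0.058 without negative control 3), a surface glycoprotein. This list had 0 members above 0 and 10 below, with a median of -0.19. For stem markers adjusted p = 0.0019, against adjusted p = 0.36 with an estimated correlation. Of 29 interferon-response genes, 0 rose, 3 fell and 26 did not pass (0 rose and 3 fell adjusted over the list alone). These 3 were IFITM3 (-0.96 ± 0.19, adjusted p up to 0.096 without each array except mock 2 and 3, and negative control 1) and IFITM1 (-0.91 ± 0.12), which block virus entry, and ISG15 (-0.69 ± 0.15, adjusted p up to 0.13 without each array except mock 2, and negative control 3), a ubiquitin-like protein. Interferon response had 6 members above 0 and 23 below, with a median of -0.058. For interferon genes adjusted p = 0.036, against adjusted p = 0.36 with an estimated correlation, and adjusted p up to 0.090 without negative control 1, or mimic 3. The median of the interferon list lay at percentile 9.22 of 10000 random lists matched on signal, within their usual range. With the arrays quantile-normalized once more the interferon list missed (adjusted p = 0.055).

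In this comparison 8 of 34 lists tested by camera passed, 5 upward and 3 downward, and with an estimated correlation 0 passed (4 at an unadjusted p under 0.05). By fry 5 passed, of which apoptosis was not among the 8, and the ribosomal protein (adjusted p = 0.090), G2/M (0.19), mesenchymal (0.060) and DNA repair (0.16) lists missed. Without mimic 3, 5 lists passed. With the mean of the small nucleolar and Cajal body RNAs as a covariate, chosen after seeing the data, the mesenchymal (adjusted p = 0.13), interferon (0.066) and DNA repair (0.084) lists missed. Among genes at or above the median signal alone, the mesenchymal (adjusted p = 0.087), G2/M (0.055) and DNA repair (0.25) lists missed. The other 26 had adjusted p-values from 0.060 to 0.999.

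The comparison of the mimic with mock shows the whole change from cells that received no small RNA. ADAMTSL1 rose most, by 1.70 ± 0.13 (3.26-fold, n = 3 per group, adjusted p = 0.00042). GLIPR1 (1.34 ± 0.11, adjusted p = 0.00060) and HMGA2 (1.25 ± 0.15, adjusted p = 0.0035) also rose, and CDK6, a kinase of G1 progression, rose by 1.12 ± 0.11. CD109 fell by 2.15 on the log2 scale (4.43-fold lower, adjusted p = 2.8e-05), its other feature giving -0.24, and MMP1 (-1.85 ± 0.087, adjusted p = 2.8e-05), interstitial collagenase, and SNAI2 (-1.71 ± 0.14, adjusted p = 0.00057) fell with it. Most of the fall of MMP1 was also seen in the negative control against mock (-1.63, adjusted p = 0.00010).

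The other largest rises were CENPQ (1.26 ± 0.24, adjusted p up to 0.092 without mock 1, or mimic 1 or 3), of the kinetochore, SCML2 (1.21 ± 0.14), a Polycomb-related protein, and TFPI (1.20 ± 0.11), an inhibitor of blood coagulation. With them rose PLAGL2 (1.14 ± 0.21, adjusted p up to 0.083 without mock 1 or 2, or any mimic array), a zinc finger transcription factor, GINS4 (1.13 ± 0.15), of the replicative helicase, whose other feature gave 0.34, and CFAP47 (1.08 ± 0.088). The other largest falls were PRUNE2 (-1.87 ± 0.18), IGFBP5 (-1.75 ± 0.14) and FBXO32 (-1.74 ± 0.13), a ubiquitin ligase of muscle wasting. With them fell SLFN5 (-1.70 ± 0.18), HEG1 (-1.64 ± 0.23), SLC49A4 (-1.49 ± 0.17) and EPAS1 (-1.48 ± 0.17), the hypoxia-inducible factor 2-alpha. For some of these genes the negative control arrays lay apart from mock in the same direction. PRUNE2 read 6.16 to 6.89 on mock and 4.68 to 5.01 on negative control arrays. SCML2 read 4.41 to 4.86 and 5.34 to 5.73, and CENPQ 2.41 to 2.73 and 3.01 to 3.96. ZEB1 fell (-0.58 ± 0.076, adjusted p = 0.0043), whereas MYB (-0.03 ± 0.10, adjusted p = 0.92), NOTCH3 (0.12 ± 0.21, adjusted p = 0.85) and CXCR4 (-0.06 ± 0.11, adjusted p = 0.85) did not pass.

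Of the 14884 genes, 580 changed, with 339 rising and 241 falling, and 2609 had an unadjusted p under 0.05. Of the 580, 362 changed at least 1.5-fold and 69 at least 2-fold. The 2 groups' arrays did not overlap for any of the 580, against 20.2% of genes tested. Among the 580, 24 were microRNA, small nucleolar or uncharacterised loci (8 rose and 16 fell). Quantile-normalized once more, 231 rose and 287 fell (44.6% rising, against 58.4%). The count was 188, 299 and 263 without mimic 1, 2 and 3, 219 without mock 1 and 376 without mock 2.

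Lists of cell cycle and ribosome genes were called upward by camera against mock. Of the 41 G2/M genes, 12 rose, 0 fell and 29 did not pass (24 rose and 0 fell adjusted over the list alone). Examples were RANGAP1 (1.00 ± 0.10), KIF20B (0.96 ± 0.16, adjusted p = 0.056 without mimic 1), a mitotic kinesin, and BIRC5 (0.79 ± 0.18, adjusted p up to 0.17 without each array except negative control 2, and mimic 2), survivin. G2/M had 37 members above 0 and 4 below, with a median of 0.41. For G2/M genes adjusted p = 7.5e-15, against adjusted p = 0.17 with an estimated correlation. Of the 29 G1/S genes, 11 rose, 0 fell and 18 did not pass (18 rose and 0 fell adjusted over the list alone). Members that rose included EXO1 (1.04 ± 0.093), MCM5 (0.96 ± 0.19, adjusted p up to 0.096 without mock 1, or any mimic array), CDC6 at 0.93 ± 0.14 and CLSPN (0.94 ± 0.16, adjusted p up to 0.054 without mimic 1 or 2), whose other feature gave 0.058. G1/S had 26 members above 0 and 3 below, with a median of 0.41. For G1/S genes adjusted p = 7.2e-13, against adjusted p = 0.17 with an estimated correlation. Of the 43 ribosomal protein genes, 6 rose, 0 fell and 37 did not pass (17 rose and 0 fell adjusted over the list alone). The largest to pass was RPL14 (0.62 ± 0.13, adjusted p up to 0.12 without each array except mock 3, and negative control 2). This ribosomal list had 43 members above 0 and 0 below, with a median of 0.35. For ribosomal proteins adjusted p = 8.2e-14, against adjusted p = 0.22 with an estimated correlation. Of 16 ribosome biogenesis genes, 5 rose, 0 fell and 11 did not pass (12 rose and 0 fell adjusted over the list alone). They were RRP12 (1.04 ± 0.18, adjusted p up to 0.076 without mock 1, or mimic 1 or 2), NOP2 (0.81 ± 0.15, adjusted p up to 0.082 without mock 1 or 2, or mimic 1 or 2), RRS1 (0.81 ± 0.16, adjusted p up to 0.098 without mock 1 or 2, or any mimic array), SRM (0.65 ± 0.12, adjusted p up to 0.078 without mock 1 or 2, or any mimic array) and BOP1 (0.44 ± 0.10, adjusted p up to 0.16 without each array), the last named after its value was seen. Ribosome biogenesis had 16 members above 0 and 0 below, with a median of 0.44. For biogenesis genes adjusted p = 1.1e-09, against adjusted p = 0.17 with an estimated correlation. The mean signal of small nucleolar and Cajal body RNAs was 6.01 ± 0.67 (SD, n = 3) in mock and 6.38 ± 0.40 in mimic arrays, beside these lists.

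Of 15 DNA repair genes, 1 rose, 0 fell and 14 did not pass (3 rose and 0 fell adjusted over the list alone). That gene was XRCC2 (0.77 ± 0.14, adjusted p up to 0.085 without mock 1 or 2, or mimic 1 or 2). DNA repair had 11 members above 0 and 4 below, with a median of 0.14. For repair genes adjusted p = 0.036, against adjusted p = 0.44 with an estimated correlation, and adjusted p up to 0.13 without mock 2 or 3, or mimic 1. Quantile-normalized once more it missed (adjusted p = 0.13). None of the 14 measured oxidative phosphorylation genes passed singly or when adjusted over the list alone. Oxidative phosphorylation had 13 members above 0 and 1 below, with a median of 0.12. For respiratory genes adjusted p = 0.038, against adjusted p = 0.60 with an estimated correlation, and adjusted p up to 0.16 without mock 1 or 3, or mimic 1 or 3. That list missed with the arrays quantile-normalized once more (adjusted p = 0.13) and centred on their medians (adjusted p = 0.054). None of the 23 small nucleolar and Cajal body RNAs passed singly or when adjusted over the list alone. This small RNA list had 18 members above 0 and 5 below, with a median of 0.32. For small RNAs adjusted p = 0.036, against adjusted p = 0.71 with an estimated correlation, and adjusted p up to 0.47 without mock 1 or 3, or mimic 1 or 3. Centred on array medians it missed (adjusted p = 0.079).

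Lists of the matrix and of mesenchymal cells were called downward by camera against mock. Of 13 collagen and matrix genes, 0 rose, 3 fell and 10 did not pass (0 rose and 4 fell adjusted over the list alone). They were the glycoprotein genes TNC (-1.40 ± 0.10), THBS1 (fell by 1.00 on the log2 scale, SE 0.12) and FBN1 (-0.62 ± 0.13, adjusted p up to 0.12 without each array except mock 2, and negative control 2). Collagen and matrix had 1 member above 0 and 12 below, with a median of -0.27. For matrix genes adjusted p = 0.00013, against adjusted p = 0.17 with an estimated correlation. Of 13 mesenchymal genes, 0 rose, 3 fell and 10 did not pass (0 rose and 4 fell adjusted over the list alone). The falls were those of SNAI2, TWIST1 (-0.78 ± 0.098) and ZEB1. The mesenchymal list had 3 members above 0 and 10 below, with a median of -0.26. For mesenchymal genes adjusted p = 0.00037, against adjusted p = 0.21 with an estimated correlation. Of 15 invasion proteases and their regulators, 0 rose, 4 fell and 11 did not pass (0 rose and 4 fell adjusted over the list alone). They were MMP1, the lysosomal protease CTSL (-1.06 ± 0.096), MMP14 (-0.84 ± 0.11) and TIMP2 (-0.94 ± 0.14), an inhibitor of metalloproteinases. Invasion proteases had 7 members above 0 and 8 below, with a median of -0.078. For invasion genes adjusted p = 0.016, against adjusted p = 0.44 with an estimated correlation, and adjusted p = 0.098 without mock 3. Of 12 TGF-beta response genes, 0 rose, 3 fell and 9 did not pass (0 rose and 3 fell adjusted over the list alone). They were TAGLN (-1.10 ± 0.12), an actin-binding protein, and CCN2 (-0.76 ± 0.11), a matricellular growth factor whose other feature gave -1.45. The third was BAMBI (-0.58 ± 0.12, adjusted p up to 0.10 without any mock array, or mimic 1 or 2), an inhibitor of the pathway. TAGLN (-1.30, adjusted p = 0.0026) and CCN2 (-0.92, adjusted p = 0.0095) also fell in the negative control against mock. The TGF-beta response had 5 members above 0 and 7 below, with a median of -0.12. For TGF-beta genes adjusted p = 0.032, against adjusted p = 0.30 with an estimated correlation, and adjusted p up to 0.096 without mock 3, or mimic 1. None of the 12 integrin and migration genes passed singly, and 1 fell when adjusted over the list alone. Integrins had 1 member above 0 and 11 below, with a median of -0.13. For integrin genes adjusted p = 0.038, against adjusted p = 0.36 with an estimated correlation, and adjusted p up to 0.10 without mock 1 or 3, or mimic 1 or 3. Against the negative control, the matrix (median -0.0015, adjusted p = 0.20, percentile 47.62 of 10000 random lists matched on signal), invasion protease (adjusted p = 0.067), TGF-beta (0.27) and integrin (0.27) lists did not pass. Of their members, THBS1 (-1.23, adjusted p = 0.0011), TNC (-0.53, 0.024), CTSL (-0.84, 0.0027) and MMP14 (-0.69, 0.013) fell there, and the rest did not pass.

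Of 10 stem and cancer markers, 0 rose, 1 fell and 9 did not pass (0 rose and 3 fell adjusted over the list alone). The gene was CD24 (-1.27 ± 0.14). Stem markers had 1 member above 0 and 9 below, with a median of -0.17. For stem markers adjusted p = 0.0046, against adjusted p = 0.18 with an estimated correlation, and adjusted p = 0.076 without mimic 1. Of 5 measured basal breast genes, 0 rose, 2 fell and 3 did not pass (0 rose and 2 fell adjusted over the list alone). They were OXTR (-1.07 ± 0.18, adjusted p up to 0.053 without mock 1, or mimic 2 or 3), the oxytocin receptor, and MYLK (-0.46 ± 0.091, adjusted p up to 0.11 without mock 1, or any mimic array), myosin light chain kinase. MYLK also fell in the negative control against mock (-0.52, adjusted p = 0.041). Basal breast had 1 member above 0 and 4 below, with a median of -0.29. For basal genes adjusted p = 0.013, against adjusted p = 0.17 with an estimated correlation. Against the negative control the basal breast (adjusted p = 0.62), oxidative phosphorylation (0.55) and small nucleolar RNA (0.36) lists did not pass. Of the 19 reported miR-150 targets, 1 rose, 2 fell and 16 did not pass (1 rose and 2 fell adjusted over the list alone). HMGA2 rose, and MMP14 (-0.84 ± 0.11) and ZEB1 fell. The target list had 9 members above 0 and 10 below, with a median of -0.015. For reported targets adjusted p = 0.47, against adjusted p = 0.71 with an estimated correlation. In this comparison 14 of 34 lists passed, 7 in each direction, against 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 13 by fry, with which the integrin (adjusted p = 0.098), DNA repair (0.10), oxidative phosphorylation (0.36) and small nucleolar RNA (0.51) lists missed. Without mimic 1, 8 lists passed, and without mock 3, 9. With the small RNA covariate the invasion protease (0.10 as adjusted p), integrin (0.10), TGF-beta (0.10), DNA repair (0.11), oxidative phosphorylation (0.45) and small nucleolar RNA (0.93) lists missed. Among genes at or above the median signal alone, oxidative phosphorylation (adjusted p = 0.24), DNA repair (0.22) and small nucleolar RNA (0.22) missed, as did DNA repair (0.083) without mock 2 and negative control 2 together. The other 20 had adjusted p-values from 0.069 to 0.976.

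**Figure D2:**
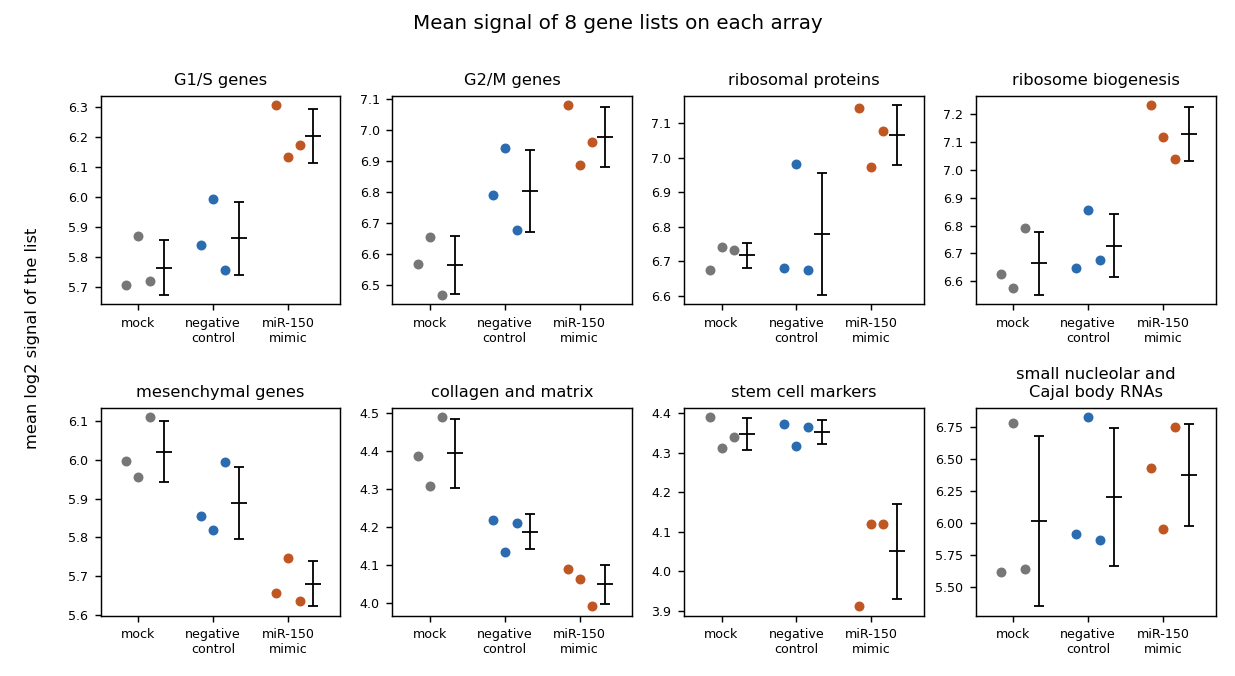
Mean log2 signal of 8 gene lists on each array (y axis, log2; each point is 1 array, bars are mean ± SD, n = 3 per group, each panel with its own scale). The G1/S and ribosome biogenesis means are higher on all 3 mimic arrays than on any control array and the mesenchymal, matrix and stem cell marker means lower, whereas the small nucleolar and Cajal body RNA means spread widely within each group.

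The comparison of the negative control with mock gives the background, the effect of a small RNA not meant to have targets. ENPP1, an enzyme that makes pyrophosphate outside the cell, rose most, by 1.27 ± 0.10 (2.41-fold, n = 3 per group, adjusted p = 0.0013). PNMA1 (1.04 ± 0.13, adjusted p = 0.078 without mock 1), ADAM19 (1.00 ± 0.12, adjusted p = 0.057 without mock 1), a membrane metalloprotease, ROR1 (0.92 ± 0.12, adjusted p = 0.081 without mock 1), a receptor for WNT5A, and TPD52L1 (0.92 ± 0.14, adjusted p up to 0.091 without each array except mock 2, and mimic 1) also rose. MMP1 fell by 1.63 and MET by 1.57 on the log2 scale (3.09-fold and 2.96-fold lower, adjusted p = 0.00010 and 0.00015). PRUNE2 (-1.64 ± 0.18), CD274 (-1.52 ± 0.14), which encodes PD-L1, and CLDN1 (-1.47 ± 0.15), a tight junction protein, fell as well. ZEB1 (-0.22 ± 0.076, adjusted p = 0.29), MYB (0.03 ± 0.10, adjusted p = 0.96), NOTCH3 (0.02 ± 0.21, adjusted p = 0.99) and CXCR4 (0.16 ± 0.11, adjusted p = 0.67) did not pass.

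Here 96 of 14884 genes changed, 25 rising and 71 falling, and 1643 had an unadjusted p under 0.05. Of the 96, 87 changed at least 1.5-fold, 18 at least 2-fold, and 3 were microRNA, small nucleolar or uncharacterised loci, all of which fell. The arrays of the 2 groups did not overlap for any of the 96, nor for 12% of all genes. With the replicate number as a block, 61 genes changed. That block was fitted over all arrays, the mimic arrays included, so it is not a paired test of these 2 groups alone. Quantile-normalized once more, 56 rose and 80 fell (41.2% rising, against 26.0%). The count was 21 and 51 without mock 1 and 3, 52, 46 and 42 without negative control 1, 2 and 3, and 57 without mimic 3.

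The lists of unfolded protein response and matrix genes were called downward by camera against mock, and G2/M genes upward. Of 11 unfolded protein response genes, 0 rose, 2 fell and 9 did not pass (0 rose and 4 fell adjusted over the list alone). The 2 were ASNS (-0.97 ± 0.14, adjusted p up to 0.093 without mock 1, or negative control 3), asparagine synthetase, and DDIT3 (-0.91 ± 0.16, adjusted p up to 0.18 without each array except mock 2), a stress transcription factor. With the replicate block DDIT3 had adjusted p = 0.12. The unfolded protein response had 3 members above 0 and 8 below, with a median of -0.23. For unfolded-protein genes adjusted p = 0.0019, against adjusted p = 0.42 with an estimated correlation. Of 13 collagen and matrix genes, 0 rose, 1 fell and 12 did not pass (0 rose and 2 fell adjusted over the list alone). The gene was TNC (-0.87 ± 0.10). The matrix list had 3 members above 0 and 10 below, with a median of -0.16. For matrix genes adjusted p = 0.0083, against adjusted p = 0.42 with an estimated correlation. Of 41 G2/M genes, 0 rose, 0 fell and 41 did not pass (1 rose and 0 fell adjusted over the list alone). The largest values were those of BIRC5 (0.60 ± 0.18, adjusted p = 0.24), CDC25C (0.60 ± 0.13, adjusted p = 0.091) and KIF20B (0.56 ± 0.16, adjusted p = 0.20). G2/M here had 39 members above 0 and 2 below, with a median of 0.22. For G2/M genes adjusted p = 7.5e-09, against adjusted p = 0.42 with an estimated correlation. The small nucleolar and Cajal body RNAs averaged 6.20 ± 0.54 (SD, n = 3) in the negative control, against 6.01 ± 0.67 in mock. These 3 of 34 lists passed by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05). The test fry, which asks whether a list moves on balance one way, called none of these 3 and 2 other lists, basal breast and NRF2 target genes. Without mock 2, negative control 1 and negative control 3, camera called 10, 6 and 10 lists. The other 31 lists had adjusted p-values from 0.053 to 0.972. The reported miR-150 targets, with 0 members passing, had adjusted p = 0.66, and their median was 0.018 and their mean -0.016.

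Against both control groups at once, the mimic arrays had 718 changed genes, 428 rising and 290 falling, and 2736 had an unadjusted p under 0.05. Of the 718, 314 changed at least 1.5-fold and 46 at least 2-fold. CD109 (-1.89 ± 0.093), SNAI2 (-1.54 ± 0.12), IGFBP5 (-1.57 ± 0.12) and FBXO32 (-1.48 ± 0.11) were among those that fell. ADAMTSL1 (1.62 ± 0.11), CFAP47 (1.41 ± 0.076), GLIPR1 (1.16 ± 0.099) and HMGA2 (1.13 ± 0.13) were among those that rose. Quantile-normalized once more, 276 rose and 382 fell (41.9% rising, against 59.6%). The count was 265, 327 and 332 without mimic 1, 2 and 3, 432 without mock 1, and 469 and 444 without negative control 1 and 3.

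Genes that changed the same way against each control numbered 220, with 119 higher, among them ADAMTSL1, CFAP47, HMGA2 and MCM2, and 101 lower, among them CD109, IGFBP5, SNAI2 and ZEB1. Independent lists of these sizes would share 5.97 and 3.42, but the comparisons share the mimic arrays and are not independent. In 100 simulations in which no group changed the most was 0. That count was all but fixed, because almost no gene passes when no group changes. It does not tell how much of the overlap comes from the shared arrays. Across genes, which are not independent replicates, the changes against the 2 controls had r = 0.67, and simulations without effects, in which the mimic arrays are likewise shared, gave 0.50. The covariance was 0.0411 against 0.00893 simulated, a difference of 0.0322. These simulations took the groups as independent, and with negative control and mock arrays correlated by number as in the data they gave r = 0.59, a covariance of 0.0105 and a difference of 0.0306. The 3 mimic arrays cannot be parted with at least 2 on each side, so part of the excess may come from the shared arrays. Quantile-normalized once more, 76 of the shared genes rose and 134 fell (36.2% rising, against 54.1%). The count was 81, 115 and 91 without mimic 1, 2 and 3, 100 and 142 without mock 1 and 2, and 119 and 109 without negative control 1 and 3.

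Another 41 genes changed one way in the mimic against the negative control and the opposite way in the negative control against mock. Of these, 30 were lower in the negative control than in mock and in the mimic arrays, as were MET, CLDN1, CRIM1, VLDLR, THOC5, MSANTD3-TMEFF1 and ASNS, and 11 were higher, as were PNMA1, ROR1, ADAM19, ENPP1 and RRM2. RRM2 passed between the controls at 0.59 ± 0.10 (adjusted p = 0.041). Without mock 1 only 21 genes in all changed between the controls, so part of the 41 rests on that array. Independent lists would share 1.60, though both comparisons use the negative control arrays. Simulations without a negative control effect gave at most 1, which was nearly fixed, because almost no gene then passes between the controls. Across genes the changes of these 2 comparisons had r = -0.34, against -0.50 simulated, and a covariance of -0.0165 against -0.00894, a difference of -0.0075. With the paired simulations they were r = -0.45, -0.00733 and -0.0091. The 41 make up 8.67% of the 473 genes that changed against the negative control, and 3 of them, CFAP47, PAQR5 and TMEM33, also changed the same way against mock. ENPP1 (0.44, adjusted p = 0.048) and NPR3 (-0.89, adjusted p = 0.0056) changed in the mimic against mock too, but the other way, as the negative control did. PAQR5, TMEM33 and NPR3 were named after their values were seen.

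**Figure D3:**
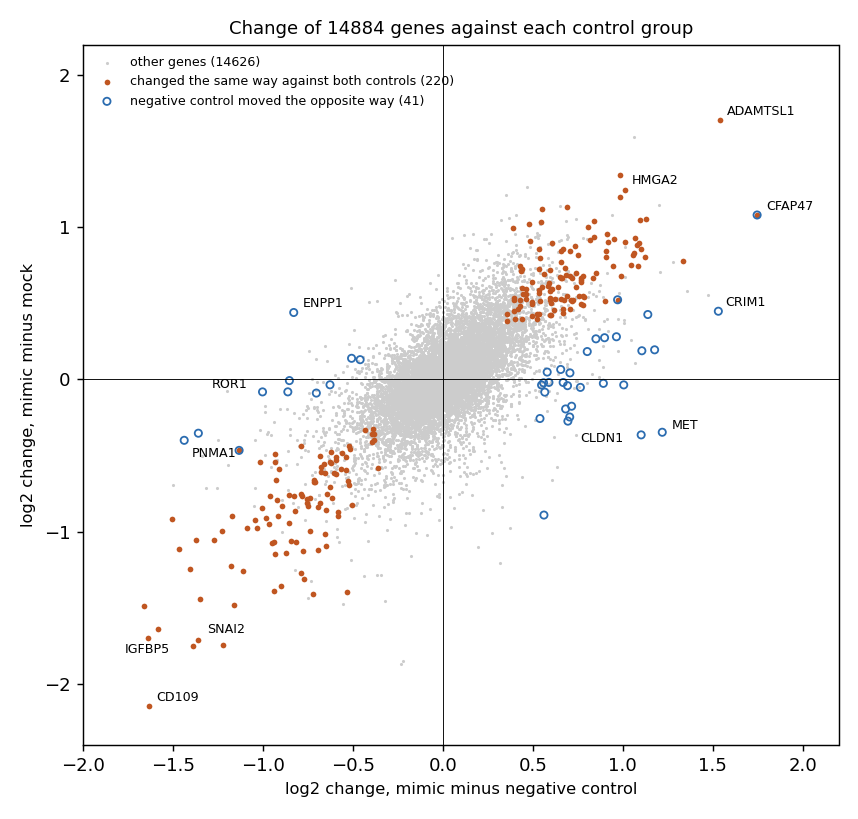
Change of 14884 genes in the mimic arrays against the negative control (x axis, log2) and against mock (y axis, log2), 1 point per gene. The 220 genes that changed the same way lie along the diagonal, and most of the 41 genes that the negative control moved the opposite way (open circles) lie closer to 0 on the y axis than on the x axis, among them MET, CLDN1 and PNMA1.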

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

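The test in this part was added after the main results were seen. Array features without a single gene symbol, which may include any with several, were left out of the comparisons of the report. They were tested on their own, with the same limma fit, adjusted over the 37519 of them. Of these, 56 changed between mimic and negative control (30 rose and 26 fell, 0.149% of them), and they are listed because they lie outside the genes compared. The largest of these rises was 2.10 and the largest fall -1.48 on the log2 scale. Against mock, 64 changed (26 rose and 38 fell), and between negative control and mock, the background, 3 did. No explanation of these features was tested.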

How the results depend on the processing

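Chosen after seeing the data were the small RNA covariate, leaving out mock 2 and negative control 2 together, the exact permutation of list means, and the replicate block for genes that changed in opposite ways, which gave 27 where 41 was the count without it. No named gene that passed changed direction under any alternative run. No called list did so with an array left out, either other scaling, the replicate block, the small RNA covariate or the filter at the median. Named genes gave 142 passing results over the 3 comparisons, where a gene can count in each; 68 of these results passed in all alternatives, and 70 were lost when some array was left out. Leaving out 1 array gave 199 to 431 genes for mimic against negative control, 188 to 650 against mock, 21 to 112 for negative control against mock, 265 to 860 against both controls and 81 to 217 the same way, and 5 to 12, 8 to 15 and 3 to 10 lists in the first 3 comparisons. In that order the counts at an adjusted p under 0.01 were 140, 144, 20, 195 and 52, a stricter threshold by construction. With at least 1.5-fold they were 362 against mock, 314 against both controls and 126 the same way. Testing all features gave 329 against mock and 118 the same way, with more tests to adjust for. Array weights gave 904 genes against mock, and the cause was not tested. Fits on the 6 arrays compared gave 251, 321 and 18 genes, from fewer samples. Genes at or above the median signal alone gave 150 genes and 5 lists for negative control against mock, from fewer genes. An estimated correlation gave 0 lists in each of the 3 comparisons, and fry 5 lists for mimic against negative control, where 8 was the count by camera. The small RNA covariate gave 5 and 9 lists for the mimic against negative control and mock, and 153 genes for negative control against mock. Without mock 2 and negative control 2, 28 genes changed between the controls, from fewer samples, and 13 lists passed against the negative control; for the lists and the other changes named here the cause was not tested.

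The replicate block gave 292 genes for mimic against negative control, 346 against mock, 61 for negative control against mock and 126 the same way, and it ended no list call of negative control against mock (adjusted p = 6.5e-10, 0.0041 and 0.0095). Mimic arrays share only a number with the control arrays, and their best matches had other numbers. In an exact two-sided permutation of list means, 3 against 6 arrays, the G1/S, ribosome biogenesis, DNA repair, mesenchymal, stem marker, interferon, p53 and apoptosis lists had the smallest p that 84 splits allow, 0.0119, adjusted 0.051. The ribosomal protein, matrix and invasion protease lists had 0.024, adjusted 0.074, so no list passed in this test. The planned seed site shift for each comparison was not run. Genes near the array median, such as MYB, have little signal over background, so a fall in them could be missed here.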

Other observations

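Chosen after the results were seen were the tests of the small RNA covariate and all tests of the genes that the negative control moved; the genes named in this paragraph and the next beyond the rule were also chosen after their values were seen. Single genes changed in lists that did not pass as a whole. Against the negative control, HMOX1 (0.85 ± 0.086), heme oxygenase 1, MCL1 (0.81 ± 0.090), an inhibitor of cell death, and BAX (0.42 ± 0.090, adjusted p up to 0.13 without each array except negative control 3), which promotes it, rose, and FOXO1 (-0.73 ± 0.15, adjusted p up to 0.11 without any negative control array, or mimic 2 or 3), a transcription factor restrained by AKT, NDRG1 (-0.72 ± 0.14, adjusted p up to 0.089 without negative control 1 or 2, or any mimic array), a hypoxia-induced gene, and IER3 (-0.70 ± 0.13, adjusted p up to 0.082 without negative control 3, or mimic 1 or 3) fell. JAG1 (0.77 ± 0.15, adjusted p up to 0.094 without mock 1, negative control 1 or 3, or mimic 2 or 3), a NOTCH ligand, XBP1 (0.50 ± 0.086, adjusted p up to 0.062 without negative control 3, or mimic 1 or 3), a transcription factor of secretory cells, and DGCR8 (0.54 ± 0.11, adjusted p up to 0.097 without each array except mock 2 and 3, and mimic 3), of the microRNA processor, rose. HMOX1 and JAG1 are among the 41 genes that the negative control changed the opposite way, and against mock they did not pass in the mimic (0.27, adjusted p = 0.13, and -0.053, adjusted p = 0.91). Between the controls they were at -0.59 (adjusted p = 0.018) and -0.82 (adjusted p = 0.048) without the replicate block. With the block, 24 of the 41 genes still changed in opposite ways. Against mock, DUSP6 (0.90 ± 0.18, adjusted p up to 0.099 without mock 1 or 2, negative control 3, or mimic 1 or 2), a phosphatase induced by ERK, and CXCL8 (0.62 ± 0.14, adjusted p up to 0.13 without each array except mock 1, and negative control 2), interleukin 8, rose, while HEY1 (-0.99 ± 0.16, adjusted p up to 0.053 without mock 1, or mimic 1), a NOTCH target, VEGFA (-0.70 ± 0.12, adjusted p = 0.056 without mock 1), a blood vessel growth factor, and FOXO1 (-0.78 ± 0.15, adjusted p up to 0.091 without mock 1, or mimic 2 or 3) fell.

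Lists of other cell types and pathways were not called by camera in either comparison of the mimic, and their values are given first against the negative control and then against mock. Among them were leukocyte markers (5 measured, median -0.087 and 0.024, adjusted p = 0.30 and 0.98), endothelial and adipocyte markers (9 measured, median -0.15 and -0.060, adjusted p = 0.060 and 0.22), epithelial genes (18 measured, median -0.035 and -0.014, adjusted p = 0.55 and 0.73) and luminal breast genes (11 measured, median -0.036 and -0.046, adjusted p = 1.0 and 0.67). Growth and stress lists were p53 targets (12 measured, median 0.017 and 0.14, adjusted p = 0.40 and 0.13), apoptosis (17 measured, median 0.11 and 0.067, adjusted p = 0.12 and 0.16), NF-kB targets (16 measured, median -0.0081 and -0.060, adjusted p = 0.70 and 0.70), NRF2 targets (7 measured, median -0.086 and -0.17, adjusted p = 0.71 and 0.16), the unfolded protein response (11 measured, median 0.13 and -0.19, adjusted p = 0.27 and 0.088) and glycolysis and hypoxia (17 measured, median -0.14 and -9.3e-05, adjusted p = 0.067 and 0.39). Signalling lists were NOTCH (22 measured, median -0.027 and -0.014, adjusted p = 0.67 and 0.39), YAP targets (12 measured, median 0.081 and 0.017, adjusted p = 0.38 and 0.77), ERK output (17 measured, median 0.073 and 0.13, adjusted p = 0.99 and 0.081) and PI3K and AKT (15 measured, median 0.035 and 0.035, adjusted p = 0.57 and 0.94). Others were cholesterol synthesis (16 measured, median 0.14 and -0.11, adjusted p = 0.27 and 0.84), lysosome and autophagy (16 measured, median 0.11 and 0.042, adjusted p = 0.36 and 0.69), microRNA machinery (8 measured, median 0.054 and 0.13, adjusted p = 0.30 and 0.087) and microRNA precursor loci (1098 measured, median -0.018 and -0.015, adjusted p = 0.55 and 0.19). By fry, apoptosis passed against the negative control and mock (adjusted p = 0.033 and 0.044), and NRF2 targets against mock (adjusted p = 0.014). The interferon list, called downward against the negative control, had a median of -0.032 against mock, with 1 of 29 members passing. There it missed by camera (adjusted p = 0.069), passed by fry (adjusted p = 0.021) and lay at percentile 21.75 of the matched random lists. The 4 antigen presentation genes measured had a median of -0.27 and -0.20, with 0 passing. Median and mean had opposite signs for basal breast and NF-kB genes against the negative control, for epithelial, leukocyte, YAP and PI3K genes against mock, and for p53, NOTCH, DNA repair and reported target genes between the controls.

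A hypothesis is that the mimic raises G1/S and ribosomal protein genes. The first axis of variation within groups held 36.9% of the variance, and 14 of its 20 highest genes were small nucleolar or Cajal body RNAs, of 22 such among 7442 genes, so the yield of small RNA in each array is a candidate technical explanation. With their mean as a covariate, the mean G1/S signal of the mimic over all 6 controls went from 0.39 ± 0.072 to 0.35 ± 0.048 (89.7% left), and that of ribosomal proteins from 0.32 ± 0.081 to 0.28 ± 0.065 (87.5% left), which argues against small RNA yield as the whole cause. Across genes, the change against the negative control rose somewhat with mean signal (Spearman's r = 0.19). In 10000 random lists matched on signal the typical median was 0.071 for G1/S and 0.065 for ribosomal proteins. The lists' own medians, 0.34 and 0.26, both lay at percentile 100 of these. That argues against a rise of bright genes as the whole cause, though random lists do not carry the correlation between a list's genes. A difference between cultures or handling days that follows the groups was not tested, and the lists' calls were lost with an estimated correlation.

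The second pattern is the 41 genes, MET, CLDN1 and PNMA1 among them, that differed between mimic and negative control and the opposite way between negative control and mock. In the direction of the call their median change was 0.80 against the negative control and 0.0080 against mock, which is 0.995% of it, a value that the choice of these genes fixes and that decides nothing. Simulations with no negative control effect gave at most 1 such gene. Without that effect almost no gene passes between the controls, so this low count was nearly fixed. It does not weigh noise of the shared arrays, which stays open. With the replicate block, a test added after seeing the data, 27 genes changed in opposite ways, 24 of them among the 41. Simulations with block effects gave at most 1, a count nearly fixed for the same reason. The negative control RNA may have effects of its own in these cells, and a difference in how those 3 samples were handled stays open, since no label separates it from the group.

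The third is lower expression of amino acid genes in the negative control, seen first in ASNS, and of 17 measured aminoacyl-tRNA synthetase genes, a list added after seeing the data, 13 lay below 0 in the negative control against mock (median -0.26, with GARS1 passing at -1.04 ± 0.14), 17 above 0 in the mimic against the negative control (median 0.35, with CARS1, GARS1, MARS1 and WARS1 passing) and 11 above 0 in the mimic against mock (median 0.12, with QARS1 passing). Of these calls, those of GARS1 against mock (adjusted p up to 0.078 without mock 1 or 3, or negative control 1), MARS1 (adjusted p up to 0.069 without negative control 1 or 3, or mimic 1 or 2), WARS1 (adjusted p up to 0.15 without each array except mock 2 and 3) and QARS1 (adjusted p up to 0.13 without each array except mock 3, negative control 2, and mimic 3) were lost when arrays were left out. The limma camera p of this list was 1.7e-06, 2.2e-10 and 0.019, against 0.11, 0.048 and 0.40 with an estimated correlation, so a rise in the mimic arrays stays open beside a fall in the negative control. A weaker amino acid response in the negative control may account for part of this. Of 19 other listed genes of that response, 8 were measured. In the negative control against mock they had a median of -0.236, with 2 above 0, 6 below and 0 passing. Their limma camera p of 0.0645 (0.34 with an estimated correlation) misses the threshold and leaves the explanation undecided, and no technical one was tested.

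Other splits of the arrays were fitted as the real ones were. Splits of 6 arrays into 3 and 3 number 10 and cannot give a share under 0.1; the real splits gave 251, 321 and 18 genes for mimic against negative control, mimic against mock and negative control against mock, and the highest other split 0 in each (1 of 10 as large each time). For lists the real splits gave 5, 14 and 3 and the highest other 13, 8 and 8, with 5, 1 and 7 of 10 as large. Other splits thus called as many lists for mimic against negative control and negative control against mock, but not for mimic against mock. Why they did was not tested, so these counts of lists do not set the real groups apart. Between the controls, whose numbers may pair the arrays, the 3 other splits that part all 3 pairs gave at most 0 genes and 4 lists. The 6 that part 1 pair gave up to 8 lists. Against both controls, 1 of 84 splits, the real one with 473 genes in a fit of 2 groups, gave as many, and the highest other gave 50. Of these, 10 splits part no pair of control arrays, as the real one does, and the highest other of them gave 1, but 10 are too few for a share under 0.05. For genes changed the same way, 1 of 100 labellings, the real one with 220, gave as many, the highest other giving 0. Chance can be excluded in both counts only if the arrays are exchangeable, which a possible pairing of the control arrays puts in doubt. The labels also do not say that the samples of a group were separate cultures. Other splits and labellings mix the groups, so any difference between groups adds to their spread and lowers their counts. These counts therefore do not exclude a chance difference between cultures.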
